A study of Homo sapiens with 6 samples.

How the data were processed

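Total RNA of HepG2 cells, an established human liver cancer line, was measured on 6 Affymetrix arrays, each hybridised with 1 biotin-labelled sample. Per the labels, 3 samples came from cells given the solvent DMSO and 3 from cells given 0.75 µM verteporfin, all collected after 24 hours. Verteporfin is a porphyrin used as a photosensitiser in photodynamic therapy and is also described as an inhibitor of the YAP-TEAD interaction; light exposure during the culture is not stated in the labels. Groups and replicate numbers were taken from the sample labels. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

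The deposited values are on the log2 scale and were made with RMA, per the submitters' processing notes; RMA corrects the background, quantile-normalises the arrays and summarises the probes of each probe set. The log2 scale was read from the range of the values, 3.17 to 13.8 with a median of 4.83 on every array. The RMA version, the array model and the probe set definitions are not given in the sources used here. The sorted values of the 6 arrays were identical (largest difference 0), so every change is relative to the distribution of each array, and a rise or fall of all transcripts together could not be seen. The values lie on steps of 0.000488 between 2 and 4, 0.000977 between 4 and 8 and 0.00195 between 8 and 16 (100% of values, tolerance 1e-06), which is far below the spread between arrays. Detection p-values and scanner intensities were not analysed here, so the number of arrays limits the precision, and dim probe sets are not separated from background. Among the genes that passed and were named by the rule given below, 18 had the mean of a group below the median signal. In DMSO these were 10: ATP6V0D2, LUCAT1, PLEKHH2, LINC01564, ALDH1L2, ERO1B, SERPINB8, DDIT3, LCN2 and HEY1. In verteporfin they were 7: SLC6A14, ODAM, AMOT, ONECUT1, CYP3A5, ALDH3A1 and APCDD1, and CD14 was the 1 below it in both. DUSP5 in DMSO (4.84) and HP and UROS in verteporfin (4.87 and 4.85) lay just above it. The log2 differences of these 18 genes describe the measured signal and are not sizes of the change in transcript.

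The table held 25582 probe sets. The platform annotation gave exactly 1 gene symbol for 24244 of them, several symbols for 0 and none for 1338. Probe sets without a symbol were left out of the gene test. For 3 symbols shared by several probe sets, the probe set with the highest mean over the 6 arrays stood for the gene, which left 24241 genes. Identifiers printed with a gene are those of its probe set. No genome coordinates are given, since no genome build is named for the array.

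Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust estimation) on the deposited log2 values, as verteporfin minus DMSO over all 6 arrays. The two-sided p-values were adjusted by Benjamini-Hochberg over the 24241 genes, with a threshold of 0.05, and SE denotes the moderated standard error of the log2 difference. A permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1, so no single-gene permutation test was used.

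Groups of genes were described with 37 gene lists holding 798 entries. A named probe set was found for 738 of these entries (735 distinct genes); the other 60 were not analysed here. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, two-sided, adjusted over the 37 lists. Camera with a correlation estimated for each list and fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, were run as alternatives. Members were counted with the p-values adjusted over all genes and again adjusted over the list alone. Lists with near-identical members, such as HSPA1A and HSPA1B, the AKR1C genes, the metallothioneins and the histones, may share probe signal between copies, and the values of those genes are uncertain for that reason.

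The genes named are the 12 highest and 12 lowest log2 changes among those past the threshold whose 3 verteporfin arrays all lay on one side of the 3 DMSO arrays. To these were added 20 genes chosen in advance. Of each list, up to 4 members with the smallest adjusted p were named, or up to 2, as values only, where none passed. Genes named outside this rule are marked as chosen after their values were seen. The groups, the test, the gene lists, the rule and the alternatives were fixed before the data were examined, except where a test is said to have been chosen later.

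The steps were tested on simulated data with the real genes' means and spreads. In 24241 simulated genes, with 50 genes at each size, 100% of changes of -2 on the log2 scale were called, 90% of changes of -1, 42% of changes of -0.5 and 56% of changes of 0.5. False calls made up 4% of all calls (6 unchanged genes). A shift of -0.5 put into the chromosomal instability list was recovered by camera with the preset correlation and, at an adjusted p of 0.00415, with an estimated correlation. The simulated genes were drawn independently and few were changed, whereas 28.5% of the real genes passed. The percentages called therefore need not hold for the real data. With no correlation between simulated genes, the list check cannot show whether the preset correlation is right. The alternatives were another normalisation and centring of the arrays, filters on dim probe sets, other handling of shared symbols, a trended robust prior, array weights, the replicate number as a block, each replicate left out, and stricter thresholds.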

Results

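Gene expression was profiled on 6 Affymetrix arrays in HepG2 cells, a liver cancer line that keeps many hepatocyte functions. The cells had been exposed for 24 hours to 0.75 µM verteporfin (3 arrays) or to its solvent DMSO (3 arrays). Values were RMA log2 levels per probe set, with 1 probe set per gene for 24241 genes. Arrays of one group correlated at 0.995 to 0.997 across genes, and arrays of different groups at 0.969 to 0.977. The first principal component separated the groups and held 83.9% of the variance. The median SD of a gene over the 3 arrays was 0.0862 log2 units in DMSO and 0.0957 in verteporfin.

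The comparison asked which transcripts changed with verteporfin. Of the genes for hepatocyte secreted proteins 21 of 25 were lower, as were 23 of 29 DNA replication genes and 14 of 15 Wnt targets, while 17 of 19 endoplasmic reticulum chaperones and 18 of 21 immediate early genes were higher. These lists passed camera with a preset correlation between genes, and with an estimated correlation their adjusted p was 0.0578 or above. The threshold was passed by 6916 genes (28.5%), of which 3460 were higher and 3456 lower. Of these, 658 were at least 2-fold higher and 730 at least 2-fold lower, and 106 and 140 were at least 4-fold higher and lower. All 3 verteporfin arrays lay on one side of all 3 DMSO arrays for 39.1% of genes, against 10% by chance. Among genes above the median signal of 4.83, 51.9% passed, against 4.59% of those below it.

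The 12 genes with the highest difference in measured log2 signal included ATP6V0D2 (5.25 ± 0.17 SE, n = 3 arrays per group here and below), a subunit of the vacuolar proton pump, and LUCAT1 (5.16 ± 0.09), a long non-coding RNA. IGFBP1, an insulin-like growth factor binding protein secreted by liver, was 24.4-fold higher (4.61 ± 0.07). PLEKHH2 (4.30 ± 0.15), LINC01564 (4.04 ± 0.30), the mitochondrial folate enzyme ALDH1L2 (3.96 ± 0.11) and HID1 (3.58 ± 0.22) were also among them. AGR2, a protein disulfide isomerase family member, rose by 3.64 ± 0.10, and the endoplasmic reticulum oxidase ERO1B by 3.54 ± 0.08. DNAJB9, a co-chaperone of the same compartment, rose by 3.54 ± 0.14, SERPINB8 by 3.51 ± 0.12 and the water and glycerol channel AQP3 by 3.45 ± 0.12. For 7 of these 12 genes (ATP6V0D2, LUCAT1, PLEKHH2, LINC01564, ALDH1L2, ERO1B and SERPINB8) the DMSO mean lay between 3.61 and 4.59, below the median signal of 4.83, where signal was not separated from background. Their values are differences of measured signal, not sizes of the change in transcript, and no order among them is drawn.

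The 12 genes with the lowest difference in measured log2 signal included several liver products. SERPINA7, the thyroxine-binding globulin, was 37.9-fold lower (-5.24 ± 0.17), the amino acid transporter SLC6A14 changed by -5.23 ± 0.15 and haptoglobin, HP, by -5.10 ± 0.18. The plasma carboxypeptidase CPB2 (-4.72 ± 0.16), the liver fatty acid binding protein FABP1 (-4.54 ± 0.21), the diacylglycerol kinase DGKK (-4.41 ± 0.06) and the steroid sulfotransferase SULT2A1 (-4.35 ± 0.19) were also lower. ODAM changed by -4.31 ± 0.07, TMT1A by -3.95 ± 0.10, the fibrinogen chain FGA by -3.94 ± 0.26 and complement factor I, CFI, by -3.91 ± 0.14. The glucose transporter SLC2A2 was 17.5-fold lower (-4.13 ± 0.47), but its verteporfin arrays varied (SD 1.12 log2 units), and without verteporfin replicate 1 it was 11.2-fold lower. The verteporfin means of SLC6A14 (4.54) and ODAM (4.79) lay below the median signal and that of HP (4.87) close to it. That of SERPINA7 was 5.21, with verteporfin replicate 1 (4.78) below the median signal. The values of these genes too are differences of measured signal, with no order drawn. The adjusted p of these 24 genes lay between 5.74e-08 and 0.000349 (limma).

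**Figure D1:**
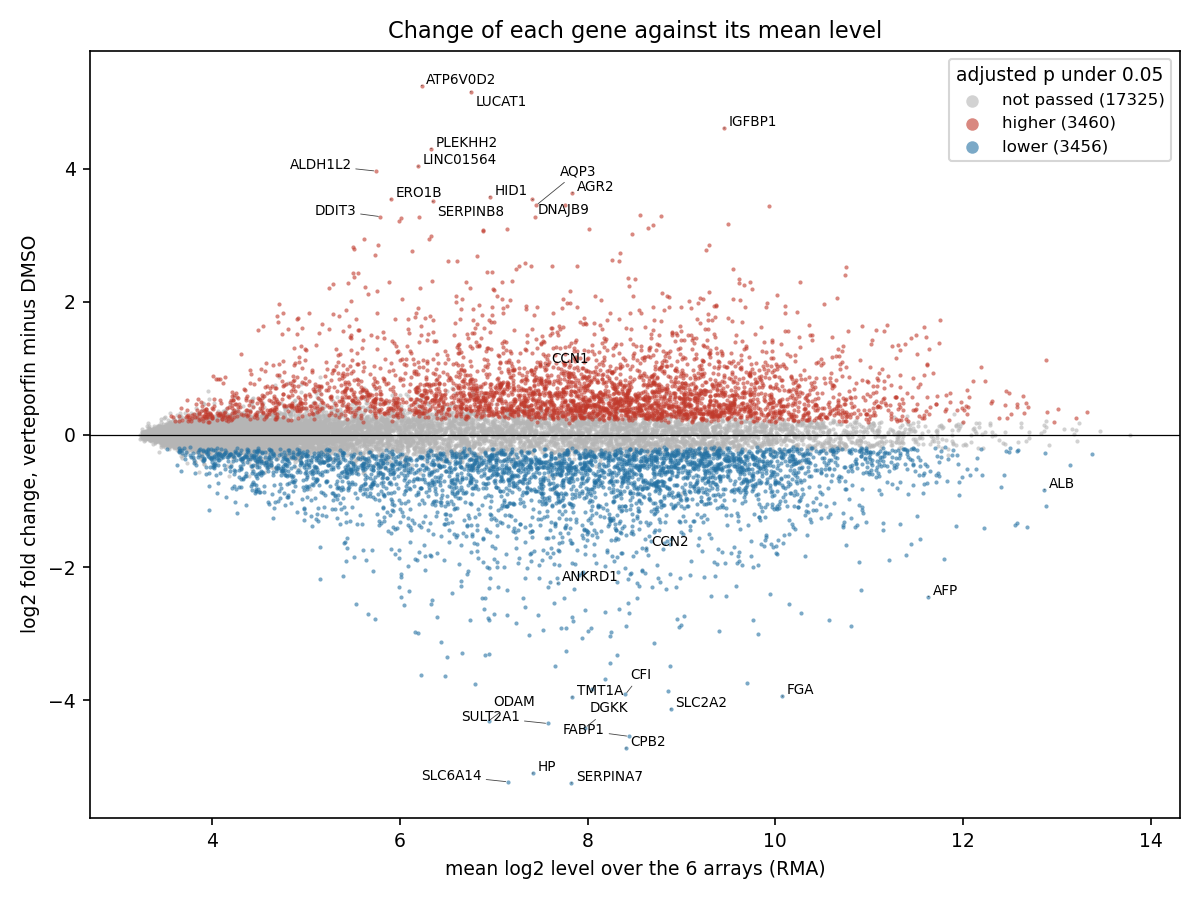
Log2 change of each of the 24241 genes (verteporfin minus DMSO, vertical axis) against its mean RMA log2 level over the 6 arrays (horizontal axis). Red and blue points mark the 3460 higher and 3456 lower genes at an adjusted p under 0.05, grey points the 17325 others, with SERPINA7 (-5.24) and ATP6V0D2 (5.25) among the labelled genes.

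The lists were compared with all other genes by camera, and 19 of the 37 passed with the preset correlation, 7 upward and 12 downward. With a correlation estimated for each list, 0 passed; the smallest adjusted p was 0.0578, 12 lists had an unadjusted p under 0.05, and fry called 26. Both adjusted p-values are given with each list.

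Verteporfin is described as a disruptor of the complex of YAP with TEAD factors, and 22 described YAP/TAZ targets were measured. They moved both ways, with 5 higher, 7 lower and 10 not passing (7 higher and 7 lower when adjusted over the list alone). ANKRD1 (-2.24 ± 0.20), CCN2, also called CTGF (-1.71 ± 0.15), the ecto-nucleotidase NT5E (-1.63 ± 0.12) and AMOTL2 (-0.43 ± 0.08) fell. The receptor kinase AXL (1.73 ± 0.08), CCN1, also called CYR61 (1.05 ± 0.11), and GADD45A (0.84 ± 0.06) rose. The list median was -0.03, and the list did not pass (adjusted p = 0.898, and 0.934 with an estimated correlation). Of the 20 Hippo pathway components, 3 were higher and 9 lower (5 and 9 adjusted over the list alone), with a median of -0.10 (adjusted p = 0.163, and 0.297 with an estimated correlation). AMOT (-1.25 ± 0.08), MAP4K4 (-0.95 ± 0.06), TEAD2 (-0.86 ± 0.09) and TEAD4 (-0.48 ± 0.06) fell. YAP1 changed by -0.32 ± 0.07 and WWTR1, which encodes TAZ, by -0.48 ± 0.12. The YAP1 call was lost without replicate 1 of both groups (adjusted p = 0.0955), and the WWTR1 call in 4 of the fits with arrays left out (adjusted p up to 0.108).

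Of the 25 genes of a published chromosomal instability signature, which largely holds cell cycle genes, 21 fell and 0 rose (24 and 0 adjusted over the list alone), with a median of -0.64. The mitotic kinesin KIF20A (-2.04 ± 0.07), the helicase subunit MCM2 (-1.83 ± 0.08), the replication clamp PCNA (-1.39 ± 0.08), TOP2A (-1.34 ± 0.07) and the transcription factor FOXM1 (-0.85 ± 0.06) were among them. The list passed (adjusted p = 5.12e-14, but 0.103 with an estimated correlation). Of 30 mitosis genes, 25 fell and 1 rose (26 and 1 adjusted over the list alone), with a median of -0.73 (adjusted p = 8.84e-14, and 0.0916 with an estimated correlation). ANLN (-1.28 ± 0.07), KIF11 (-1.24 ± 0.07), DLGAP5 (-1.23 ± 0.07) and the cyclin CCNA2 (-1.07 ± 0.06) had the smallest p; the member that rose, CEP55 (0.61 ± 0.06), is named after its value was seen. Of 29 DNA replication genes, 23 fell and 1 rose (24 and 1 adjusted over the list alone), with a median of -1.0 (adjusted p = 1.64e-14, and 0.0578 with an estimated correlation). MCM6 (-1.63 ± 0.07), GINS2 (-1.60 ± 0.06), MCM3 (-1.59 ± 0.08) and GINS1 (-1.42 ± 0.07) fell, while the replication licensing factor CDC6, also named after its value was seen, rose by 1.09 ± 0.10. Of 15 replication-dependent histones, 9 fell and 1 rose (9 and 1 adjusted over the list alone), with H1-5 at -3.29 ± 0.13, H2BC13 at -1.52 ± 0.12, H2AC8 at -1.41 ± 0.10 and H2BC17 at -1.01 ± 0.10 (adjusted p = 0.000351, and 0.339 with an estimated correlation).

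The p53 targets did not pass as a list, with 7 of 23 higher and 6 lower (9 and 6 adjusted over the list alone; adjusted p = 0.730, and 0.795 with an estimated correlation). The secreted stress factor GDF15 (1.65 ± 0.06), PLK3 (1.61 ± 0.10) and the cell cycle inhibitor CDKN1A (1.38 ± 0.07) rose, and SESN1 fell (-1.20 ± 0.09). Of 19 apoptosis regulators, 10 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.00715, and 0.171 with an estimated correlation). The members that rose act on both sides of cell death: PMAIP1 (1.91 ± 0.12) and BAK1 (0.69 ± 0.09) are known to promote it, and MCL1 (1.16 ± 0.07) and BCL2L2 (1.0 ± 0.12) to oppose it.

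Of 25 ATF4 and amino acid response genes, 20 rose and 4 fell (20 and 4 adjusted over the list alone), with a median of 1.17 (adjusted p = 4.62e-11, and 0.189 with an estimated correlation). DDIT3, which encodes the transcription factor CHOP, was higher by 3.28 ± 0.17 in measured signal, from a DMSO mean of 4.15 below the median signal. SESN2 (3.15 ± 0.11), asparagine synthetase ASNS (2.05 ± 0.07) and TRIB3 (1.93 ± 0.07) rose as well. Of 19 chaperones and degradation factors of the endoplasmic reticulum, 17 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 1.35 (adjusted p = 8.50e-14, and 0.103 with an estimated correlation). DNAJB9, HERPUD1 (2.52 ± 0.10), MANF (1.92 ± 0.08) and HYOU1 (1.72 ± 0.06) had the smallest p. The member that fell was XBP1 (-0.54 ± 0.07), a transcription factor of this response, named after its value was seen. Among heat shock genes, 6 of 19 were higher and 3 lower (6 and 3 adjusted over the list alone; adjusted p = 0.323, and 0.580 with an estimated correlation). DNAJB4 (1.92 ± 0.12), HSPA1A (1.26 ± 0.12) and BAG3 (0.96 ± 0.09) rose, and HSPB1 fell (-0.93 ± 0.10).

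**Figure D2:**
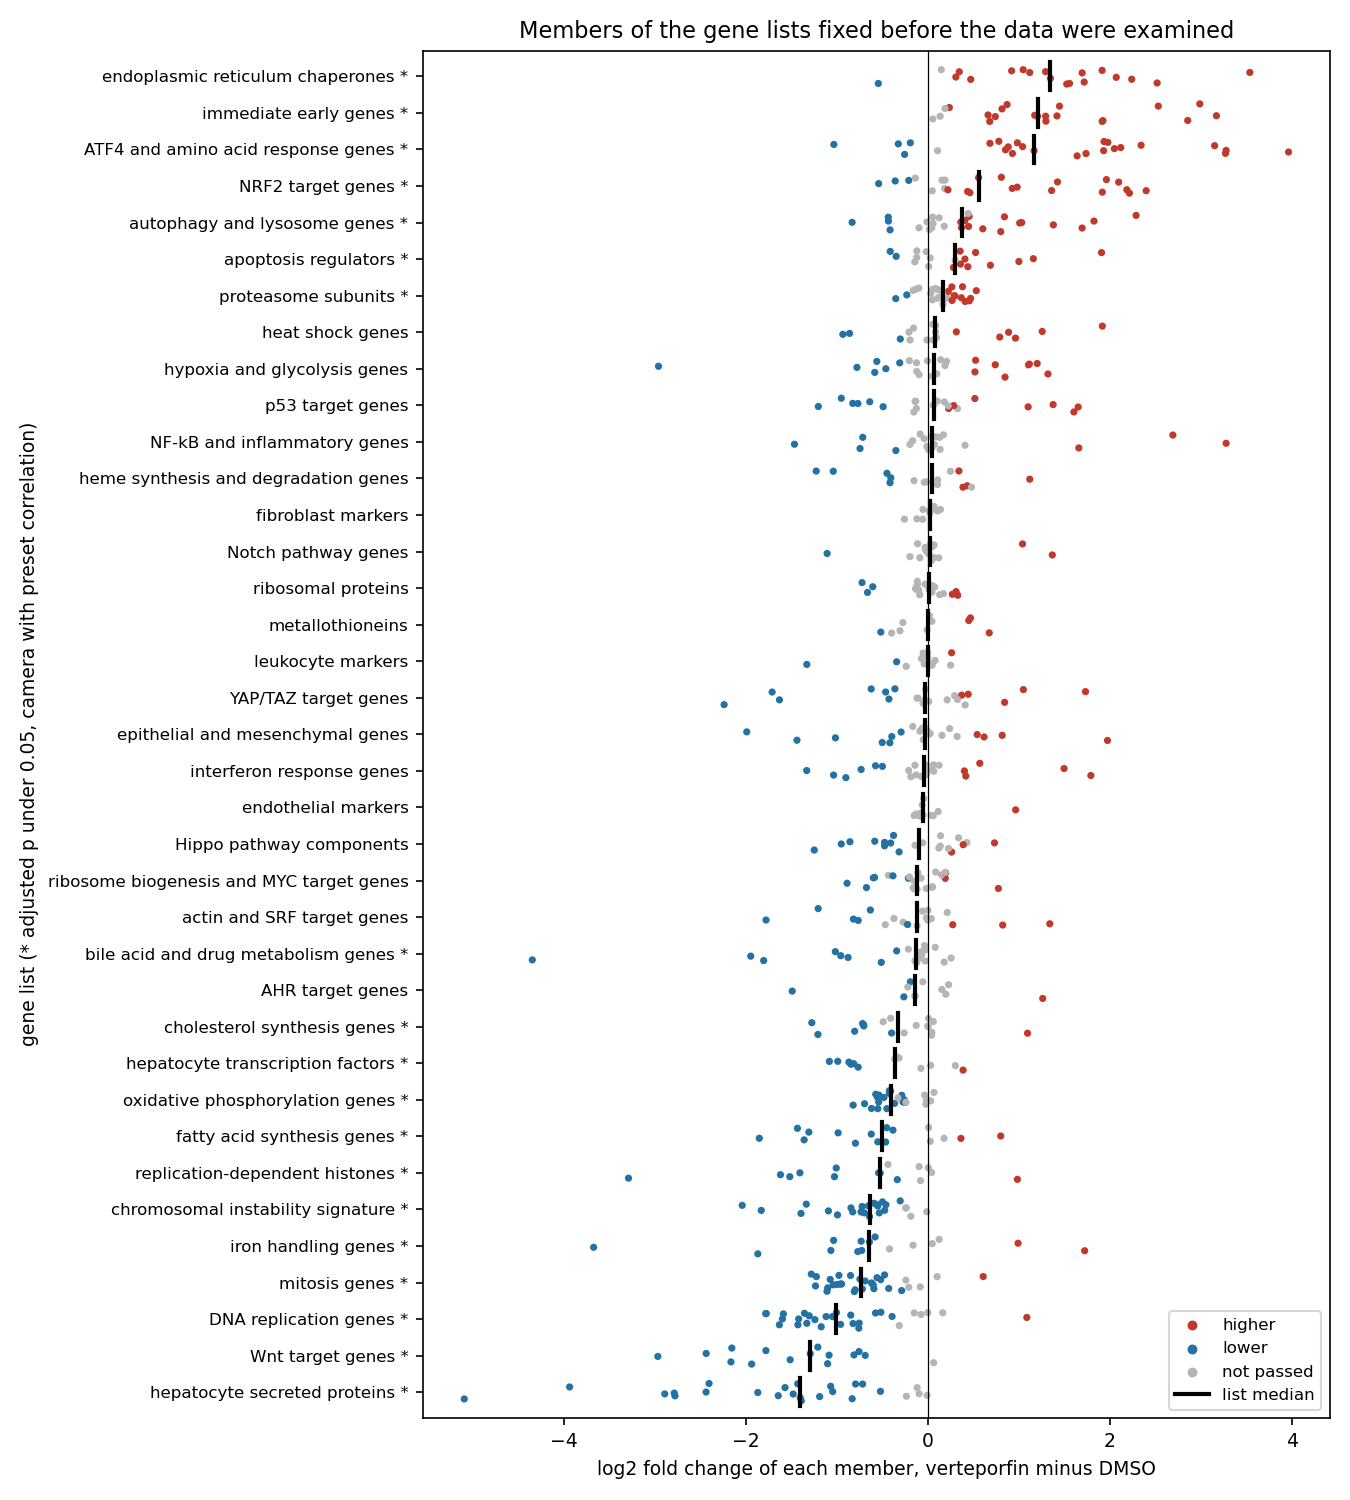
Log2 change of every measured member of the 37 gene lists (horizontal axis, verteporfin minus DMSO, means of 3 arrays per group), with 1 row per list and the list median marked. Medians run from -1.40 for hepatocyte secreted proteins to 1.35 for endoplasmic reticulum chaperones, and the YAP/TAZ targets spread from -2.24 to 1.73 around a median of -0.03.

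NRF2 targets, which act against oxidative stress, were higher for 15 of 23 members and lower for 3 (18 and 4 adjusted over the list alone), with a median of 0.56 (adjusted p = 1.55e-07, and 0.0578 with an estimated correlation). The cystine transporter SLC7A11 (2.40 ± 0.09), SRXN1 (2.19 ± 0.07), the glutathione synthesis enzyme GCLC (1.96 ± 0.07) and TXNRD1 (1.43 ± 0.06) rose. HMOX1, the inducible heme oxygenase in the same list, fell by 0.54 ± 0.07, and NQO1 was at -0.14 ± 0.06, which did not pass (adjusted p = 0.127). Of 28 autophagy and lysosome genes, 15 rose and 4 fell (16 and 4 adjusted over the list alone; adjusted p = 0.000301, and 0.187 with an estimated correlation). WIPI1 (2.29 ± 0.08), the protease CTSL (1.83 ± 0.07), ATG4A (1.70 ± 0.08) and the autophagy receptor SQSTM1 (1.38 ± 0.07) had the smallest p. Of 26 proteasome subunits, 11 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 0.16 (adjusted p = 0.00751, and 0.477 with an estimated correlation). PSMD8 (0.53 ± 0.07), PSMD14 (0.47 ± 0.06) and PSMD12 (0.46 ± 0.07) rose and PSMD1 fell (-0.35 ± 0.06); the list's call was also lost with genes below the median signal left out (adjusted p = 0.0635).

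Immediate early genes, the early transcripts of growth factor and stress signalling, were higher for 18 of 21 members and lower for 0 (18 and 0 adjusted over the list alone), with a median of 1.21 (adjusted p = 4.38e-14, and 0.0578 with an estimated correlation). The phosphatase DUSP5 (2.99 ± 0.10), EGR1 (2.86 ± 0.10), the mRNA decay factor ZFP36 (2.53 ± 0.11) and SPRY4 (1.92 ± 0.08) had the smallest p. The DMSO mean of DUSP5 (4.84) lay close to the median signal, so its value is a difference of measured signal. MYC rose by 0.74 ± 0.07. Among 21 NF-kB and inflammatory genes, 3 were higher and 4 lower (3 and 4 adjusted over the list alone; adjusted p = 0.859, and 0.908 with an estimated correlation). The siderophore-binding LCN2 was higher by 3.28 ± 0.11 in measured signal, from a DMSO mean of 4.57 below the median signal. The chemokine CXCL8 (2.69 ± 0.19) and NFKB2 (1.66 ± 0.18) rose, and the NF-kB inhibitor TNFAIP3 fell (-1.47 ± 0.09). Among 22 interferon response genes, 5 were higher and 6 lower (5 and 7 adjusted over the list alone; adjusted p = 0.701, and 0.742 with an estimated correlation). IRF9 (1.79 ± 0.16), IRF1 (1.50 ± 0.16) and TAP1 (0.57 ± 0.07) rose and IFI35 fell (-1.04 ± 0.09).

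Of 25 genes for proteins that hepatocytes secrete, 21 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -1.40 (adjusted p = 2.68e-18, and 0.118 with an estimated correlation). Beside HP and FGA, APOC3 (-2.89 ± 0.07), the fibrinogen chain FGG (-2.79 ± 0.06), alpha-fetoprotein AFP (-2.44 ± 0.14), transferrin TF (-1.87 ± 0.07) and albumin ALB (-0.83 ± 0.06) fell. Of 13 hepatocyte transcription factors, 6 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.00221, and 0.103 with an estimated correlation). PROX1 (-1.08 ± 0.10), ONECUT1 (-0.99 ± 0.08), CEBPA (-0.85 ± 0.10) and RXRA (-0.77 ± 0.07) fell. Of 20 bile acid and drug metabolism genes, 8 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.13 and 8 members above the median signal (adjusted p = 0.00201, and 0.103 with an estimated correlation). Beside SULT2A1, the bile acid enzyme CYP27A1 (-1.95 ± 0.10), ADH4 (-1.81 ± 0.14) and CYP3A5 (-0.88 ± 0.10) fell.

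Of 16 fatty acid synthesis genes, 11 fell and 2 rose (11 and 3 adjusted over the list alone; adjusted p = 0.000592, and 0.189 with an estimated correlation). PNPLA3 (-1.85 ± 0.16), the desaturase SCD (-1.43 ± 0.07), ACACB (-1.31 ± 0.09) and GPAM (-0.99 ± 0.08) fell. Of 18 cholesterol synthesis genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.00331, and 0.144 with an estimated correlation). TM7SF2 (-1.28 ± 0.09), EBP (-1.21 ± 0.09) and HMGCS1 (-0.70 ± 0.06) fell, and the sterol carrier STARD4 rose (1.10 ± 0.08). Of 25 oxidative phosphorylation genes, 18 fell and 0 rose (20 and 0 adjusted over the list alone), with a median of -0.41 (adjusted p = 3.52e-07, and 0.103 with an estimated correlation). COX7B (-0.70 ± 0.07), UQCRC2 (-0.62 ± 0.06), ATP5F1C (-0.55 ± 0.06) and ATP5PO (-0.54 ± 0.06) fell.

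Of the iron handling genes, 9 of 15 were lower and 2 higher (10 and 2 adjusted over the list alone; adjusted p = 0.000484, and 0.189 with an estimated correlation). Ceruloplasmin CP (-3.67 ± 0.12) and the iron hormone HAMP (-1.04 ± 0.09) fell with TF, which the secreted protein list also holds, and the iron exporter SLC40A1 rose (1.72 ± 0.09). Heme synthesis and degradation genes moved both ways, with 4 of 16 higher and 5 lower (5 and 5 adjusted over the list alone; adjusted p = 0.974, and 0.974 with an estimated correlation). BLVRB rose (1.12 ± 0.07), ALAD (-1.23 ± 0.17), CPOX (-1.04 ± 0.07) and UROS (-0.41 ± 0.08) fell, and the list's median (0.04) and mean (-0.03) differed in sign. ALAS1, the first enzyme of heme synthesis, rose by 0.43 ± 0.09, a call lost without replicate 3 of both groups (adjusted p = 0.0641). Of 10 metallothionein genes with their regulator and the zinc exporter, 3 were higher and 1 lower (3 and 2 adjusted over the list alone; adjusted p = 0.840, and 0.869 with an estimated correlation). MTF1 (0.67 ± 0.07), MT2A (0.47 ± 0.11) and MT1X (0.45 ± 0.08) rose and MT1G fell (-0.52 ± 0.14); the calls of the last 3 were each lost in at least 1 fit with arrays left out (adjusted p up to 0.134). Of 11 AHR targets, 1 was higher and 3 lower (2 and 3 adjusted over the list alone; adjusted p = 0.589, and 0.742 with an estimated correlation). CYP1A1 rose (1.26 ± 0.22), NEDD9 fell (-1.49 ± 0.13), and the smaller falls of ALDH3A1 (-0.26 ± 0.07) and SLC7A5 (-0.19 ± 0.06) were lost in 7 and 11 of 18 alternatives (adjusted p up to 0.206).

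Wnt targets were lower for 14 of 15 members and higher for 0 (14 and 0 adjusted over the list alone), with a median of -1.29 (adjusted p = 1.82e-10, and 0.144 with an estimated correlation). TNFRSF19 (-2.97 ± 0.09), the Wnt inhibitors NKD1 (-1.78 ± 0.13) and NOTUM (-1.29 ± 0.10), and APCDD1 (-0.76 ± 0.06) had the smallest p. The Notch genes did not pass as a list, with 2 of 16 higher and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.773, and 0.835 with an estimated correlation). The ligand JAG1 rose (1.37 ± 0.06) and SOX9 fell (-1.11 ± 0.10). HEY1 was higher by 1.04 ± 0.15 in measured signal, from a DMSO mean of 4.13 below the median signal. Of 24 hypoxia and glycolysis genes, 8 were higher and 6 lower (9 and 7 adjusted over the list alone; adjusted p = 0.633, and 0.685 with an estimated correlation). NDRG1 (1.20 ± 0.07), PFKP (1.12 ± 0.09) and KDM3A (0.74 ± 0.06) rose, and the glucose transporter SLC2A3 fell (-2.96 ± 0.16).

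**Figure D3:**
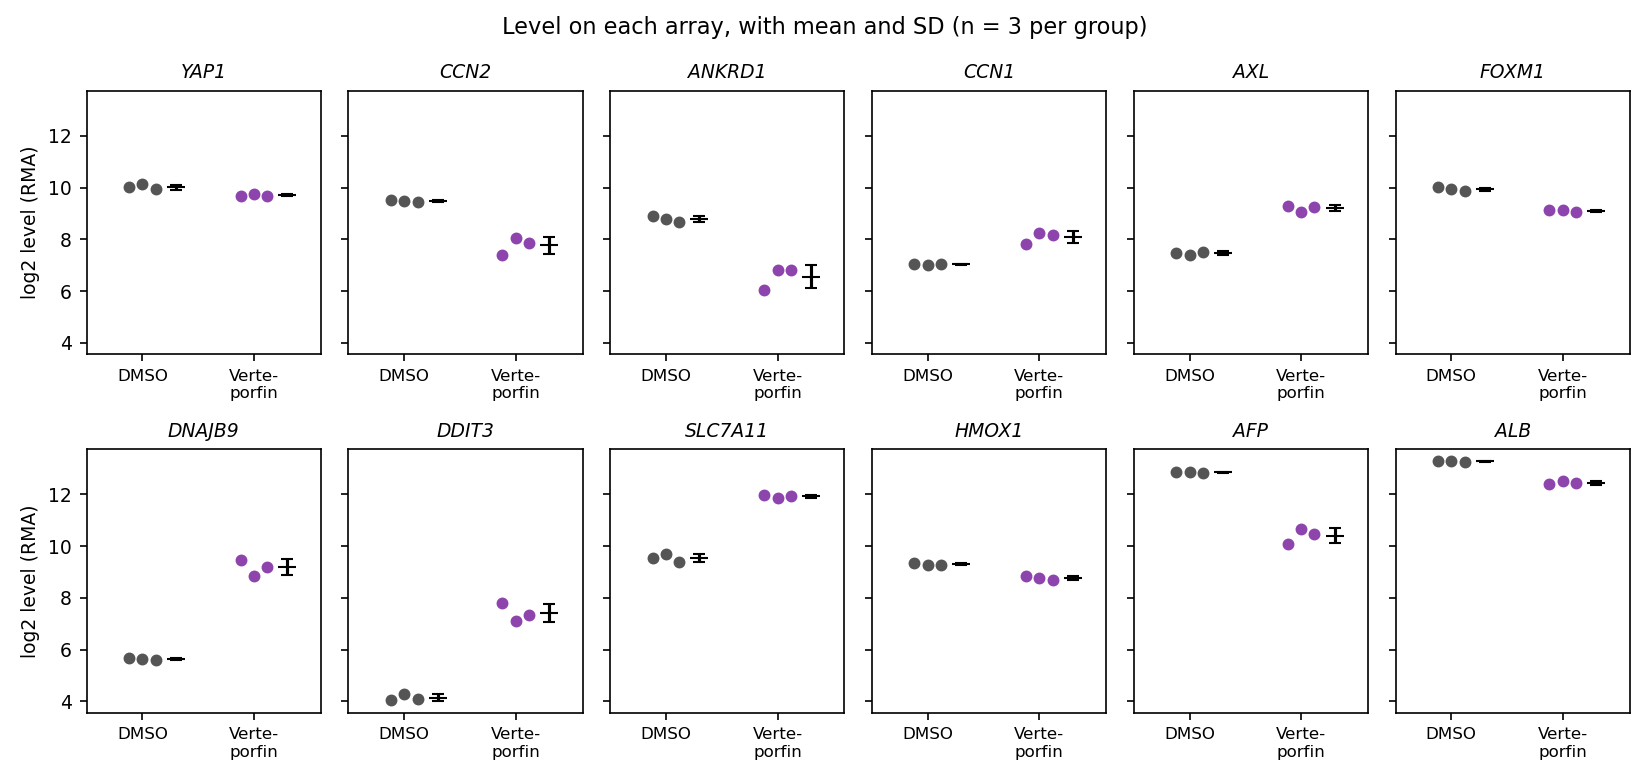
RMA log2 level (vertical axis) of 12 of the named genes on each of the 6 arrays, with 1 point per array and, beside the 3 points of each group, a bar for the mean and 1 SD. DNAJB9 (log2 change 3.54), DDIT3 (3.28), SLC7A11 (2.40), AXL (1.73) and CCN1 (1.05) were higher with verteporfin, and YAP1 (-0.32), CCN2 (-1.71), ANKRD1 (-2.24), FOXM1 (-0.85), HMOX1 (-0.54), AFP (-2.44) and ALB (-0.83) were lower.

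Lists of the cytoskeleton, cell adhesion and ribosome did not pass. Of 19 actin and SRF targets, 3 were higher and 6 lower (4 and 8 adjusted over the list alone; adjusted p = 0.136, and 0.761 with an estimated correlation). FHL2 rose (0.82 ± 0.08), and MYL9 (-1.21 ± 0.12), CALD1 (-0.77 ± 0.07) and ACTN4 (-0.63 ± 0.06) fell. Of 22 epithelial and mesenchymal genes, 4 were higher and 7 lower (5 and 7 adjusted over the list alone; adjusted p = 0.486, and 0.677 with an estimated correlation). Occludin OCLN rose (1.97 ± 0.08), and SPARC (-1.99 ± 0.09) and both cadherins, CDH2 (-1.44 ± 0.08) and CDH1 (-1.02 ± 0.06), fell. Of 25 ribosomal protein genes, 3 were higher and 3 lower (2 and 3 adjusted over the list alone; adjusted p = 0.822, and 0.869 with an estimated correlation), and the median (0.01) and mean (-0.05) differed in sign. RPL37 (-0.72 ± 0.14), RPL22 (-0.66 ± 0.14) and RPS23 (-0.61 ± 0.07) fell and RPS13 rose (0.33 ± 0.07); apart from RPS23 these calls were lost in fits with arrays left out (adjusted p up to 0.0746). Of 23 ribosome biogenesis and MYC targets, 3 were higher and 6 lower (3 and 8 adjusted over the list alone; adjusted p = 0.136, and 0.677 with an estimated correlation). RRP12 rose (0.78 ± 0.07), and UTP20 (-0.89 ± 0.08), FBL (-0.68 ± 0.07) and POLR1A (-0.59 ± 0.08) fell.

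Markers of other cell types were mostly near the low end of the scale and did not pass as lists. Of 12 fibroblast markers, 0 passed and 1 had an unadjusted p under 0.05 (0 adjusted over the list alone; limma); PDGFRB was at -0.26 ± 0.09 and THY1 at 0.14 ± 0.08 (list adjusted p = 0.974, and 0.974 with an estimated correlation). Of 12 endothelial markers, 1 was higher, the adhesion protein ESAM (0.97 ± 0.12), and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.859, and 0.888 with an estimated correlation). Median, mean and test did not share a sign in either of these lists. Of 14 leukocyte markers, LYZ (-1.33 ± 0.12) and CD14 (-0.34 ± 0.07) were lower and CD68 (0.26 ± 0.06) was higher, 1 higher and 2 lower in all (1 and 2 adjusted over the list alone; adjusted p = 0.701, and 0.742 with an estimated correlation). The log2 level of LYZ in DMSO was 13.24, among the highest on the arrays, and the calls of CD14 and CD68 were lost in fits with arrays left out (adjusted p up to 0.106).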

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

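Centring the arrays on the genes above the median signal was chosen only after the values were seen; all other alternatives were planned. Requiring a 2-fold change beside the adjusted p left 1388 genes, 658 higher and 730 lower, and estimating the correlation in camera left 0 lists; the first follows from the added criterion, and the cause of the second was not tested. None of the named genes and none of the 19 called lists changed direction under any alternative run; among the lists that did not pass, the median of some changed sign, and fry put the YAP/TAZ targets and the fibroblast and endothelial markers upward where camera put them downward. With 1 array left out, 5974 to 6626 genes passed (2989 to 3406 higher, 2985 to 3220 lower), and with the same replicate number left out of both groups 5028 to 5983 (2474 to 3074 higher, 2554 to 2909 lower); 19 or 20 lists passed in these fits. A threshold of 0.01 gave 5067 genes, a trended robust prior 7054, array weights 7070, filters on dim probe sets 6961 and 6813, every probe set tested alone 7162, and the added centring 6917. Repeating the quantile normalisation and centring on the median changed nothing, since the sorted values already were identical, and these 2 settings say nothing about stability. The added centring says little either, since the medians it used ran only from 7.5957 to 7.59766. Averaging shared probe sets could alter only 3 symbols. All these settings are still counted among the alternatives. The replicate numbers did not pair the arrays: deviations from the group means correlated at -0.0161, -0.109 and -0.0116 for same-numbered arrays. With the replicate block, 6359 genes (3209 higher, 3150 lower) and 19 lists passed. Of the 173 named genes 170 passed; 14 of these lost the call in at least 1 alternative at the same threshold, and 0 changed direction. These were ALAS1, ALDH3A1, CD14, CD68, MT1G, MT1X, MT2A, PSMD1, RPL22, RPL37, RPS13, SLC7A5, WWTR1 and YAP1. Apart from the estimated correlation, 18 of the 19 called lists passed in all alternatives run, and the proteasome list was lost with dim genes left out (adjusted p = 0.0635). Below the median signal 4.59% of genes passed, and since no detection values were analysed here, low signal and the lack of a change were not separated there.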

Other observations

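The additional gene lists and families of the first paragraphs, and the tests of dilution by other cells, of loss confined to secreted proteins and of a general fall of cell cycle genes, were chosen only after the results were seen. Cytosolic tRNA synthetases, which charge tRNAs with amino acids, were higher for 11 of 19 members and lower for 1, with a median of 0.31 (camera adjusted p = 2.48e-05 over 4 such lists, and 0.113 with an estimated correlation). WARS1 was 4.88-fold higher (2.29 ± 0.06 SE, n = 3 arrays per group), and SARS1 (1.40 ± 0.09), CARS1 (1.17 ± 0.08) and MARS1 (1.10 ± 0.08) rose, while QARS1 fell (-0.50 ± 0.07); 3 of the members are also in the ATF4 list. Of 6 EGF receptor ligands, EREG (3.29 ± 0.11) and HBEGF (1.83 ± 0.14) rose and 4 did not pass (list adjusted p = 0.0657, and 0.132 with an estimated correlation). Of 8 transcripts described as targets of decay by the endoplasmic reticulum nuclease IRE1, 5 fell and 0 rose. Among them were DGAT2 (-2.18 ± 0.32), SPARC (-1.99 ± 0.09) and BLOC1S1 (-1.43 ± 0.16). The camera adjusted p was 0.000324, and 0.0812 with an estimated correlation. SPARC and PDGFRB are also in lists described above, so this p-value draws partly on values already seen, and the list was not tested without them.

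Grouping genes by the letters of their symbols gave 168 families of at least 15 genes, of which 5 passed camera with the preset correlation. Symbols alone set the families, so non-coding transcripts named after a gene were counted with it. Genes with symbols in SEC, many of which serve vesicle transport, rose for 14 of 31 members and fell for 0 (adjusted p = 0.00112), with SEC24D at 1.47 ± 0.09. Symbols in TRAPPC, with genes of vesicle tethering, rose for 11 of 17 and fell for 1 (0.0115). Those in ATG, with genes of autophagy, rose for 11 of 18 and fell for 0 (0.00332). Those in DNAJB, with genes of co-chaperones, rose for 6 of 15 and fell for 0 (0.0470). Symbols in ALDH, with genes of aldehyde dehydrogenases, fell for 12 of 22 and rose for 2 (0.00332). ALDH5A1 was at -1.96 ± 0.08 against ALDH1L2 at 3.96 ± 0.11. With an estimated correlation each of these 5 families had a camera adjusted p of 0.728. Members such as ATG4A, DNAJB4, DNAJB9 and ALDH1L2 are also in lists described above. The p-values of the ATG, DNAJB and ALDH families thus draw partly on values already seen, and these families were not tested without such members. Of the 1338 probe sets without a gene symbol, 269 passed, 133 higher and 136 lower.

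The fall of hepatocyte secreted protein genes was set against 3 explanations. For a signal-dependent shift from the normalization, random lists matched on mean level were drawn. The list median of -1.40 lay at percentile 0 of 10000 such lists, whose central 95% ran from -0.20 to 0.21. Genes of similar level thus did not share the fall. The sorted values were already identical and the list already called against all genes, so this percentile is little independent evidence on the normalization. RNA of other cell types diluting the HepG2 RNA is argued against by the markers of 3 other cell types. Their median log2 change was -0.00138 (95% bootstrap interval -0.06 to 0.03). The intervals here and below resample the genes of a list as if independent and hold no error between arrays. The marker median includes LYZ and CD68, already at 13.24 and 10.23 in DMSO. Only 2 of 12 fibroblast, 3 of 12 endothelial and 5 of 14 leukocyte markers lay above the median signal. Of all these markers, ESAM (0.97) and CD68 (0.26) passed as higher and LYZ (-1.33) and CD14 (-0.34) as lower. A loss confined to mRNAs of secreted proteins is argued against by intracellular liver proteins above the median signal, whose median was -1.23 (interval -1.86 to -0.34). These 17 genes include FABP1, a binding protein already seen among the lowest genes when the list was made; the 16 enzymes without it had a median of -1.14 (interval -1.78 to -0.34). Over all 29 such enzymes, at any signal, the median was smaller, at -0.28 (interval -0.74 to -0.05), with 15 lower, 2 higher and 12 not passing. By which route verteporfin lowered these transcripts was not tested, and not all liver transcripts fell, since IGFBP1 (4.61) and TAT (1.63) rose.

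The YAP/TAZ target genes moved both ways, and it was asked whether members near background could not fall. Of the 17 members above the median signal in DMSO, 5 passed as higher and 6 as lower, so directions were mixed above that level too. The counts leave out the members below that level. Of these, TGFB2, named after its value was seen, passed as lower (-0.46 ± 0.09) from a DMSO mean of 4.24. A dimmer member could thus fall in measured signal. The others below that level did not pass, and whether they could fall is not shown. No background level was measured. Which regulators act on the members that rose was not tested.

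The fall of the chromosomal instability signature may be a general fall of cell cycle genes. The signature median was 0.181 above the median of 59 mitosis and replication genes (two-sided permutation over genes, p = 0.212), so the data give no sign of a larger fall in the signature. The signature median lay at percentile 0 of 10000 level-matched lists (central 95% from -0.23 to 0.26), so genes of similar level did not share the fall. As for the secreted proteins, this is little independent evidence on a signal-dependent shift from the normalization. An effect on cell number or on the share of dividing cells was not measured and stays open.

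The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. As many genes as in the real split (6916) were given by 1 of 10 splits, the real one, and the highest count of the other splits was 0 by limma, with up to 742 genes at an unadjusted p under 0.05. As many lists as in the real split (19) were also given by 1 of 10 splits, and the highest other count was 12 lists with the preset correlation and 0 with an estimated one. Each other split exchanges 1 array per group. Part of the treatment difference thus stays between its groups, and the rest widens the spread within them. Low gene counts in the other splits can follow from this alone, so these counts are no evidence against chance.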
